A study of Mus musculus with 16 samples.

How the data were processed

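The series holds 16 mouse samples in 8 groups: cells and exosomes of the stromal lines AFT024 and BFC012, each as polyA RNA and as small RNA. Per the labels, total RNA was extracted with Trizol, polyA RNA was purified with oligo-dT for mRNA libraries, the remaining RNA was used for small RNA libraries, and libraries were sequenced on a HiSeq instrument. Exosome RNA was pooled and split for technical sequencing replicates, which were merged per the design text. The deposited tables hold 1 merged value per group. The culture serum is not stated in the labels.

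The submitters' processing notes name TopHat, Cufflinks and Bowtie with the mouse genome build mm10, with no role or version for each. The tool that counted reads per gene and the annotation release are not given in the sources used here. The deposited polyA table of all groups holds FPKM per the file headers (fragments per kilobase of transcript and per library size), computed by the authors. The deposited small RNA table of all groups holds a normalized signal, which is reads per miRNA arm that the authors divided by a size factor set over the 4 small RNA groups. The authors' deposited pairwise tables hold reads divided by a size factor of the compared pair, except that those of small RNA between the lines hold whole counts, named normalized reads per the file headers. Each pairwise table also holds the authors' log2 ratio, p-value and q-value from a Fisher test on merged reads. All values use decimal commas. The authors' deposited polyA table of AFT024 exosomes against cells lists 16224 genes and the others 43629.

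Whole reads were recovered by dividing each column by its smallest step. In every pairwise table and in the small RNA table of all groups 100% of values were whole within 0.01 reads, and a group's reads were equal in all tables that hold it. The recovered totals, given in the report, are the depth of each group. The FPKM table lists 24544 genes and 0 on chromosomes X, Y and M. Reads of genes not in it made up 2.07%, 2.08%, 2.95% and 2.85% of the reads of AFT024 exosomes, BFC012 exosomes, AFT024 cells and BFC012 cells. All 37 mitochondrially encoded genes had 0 reads in the read tables. Of the columns with values per group, 0 were left unused.

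PolyA genes were kept at 1 FPKM or more in at least 1 group (14969 genes, 11069 of them protein-coding) and miRNA arms at a value of 10 or more (818 of 2386, of which 164 are named by a numbered locus and can share a mature sequence). By symbol, 99.3% of the kept genes matched 1 gene of the read tables. Of these genes, 393 were listed at 0 FPKM in a group that had 20 or more reads. Log2 ratios were taken after adding 1 to the deposited values. The comparisons were exosomes against cells in each line, AFT024 against BFC012 in cells and in exosomes, and the difference between the lines in exosome-against-cell change. With 1 value per group no test was made, and a change of 2-fold or more was counted. The authors' q-values were counted under 0.05.

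Read ratios between groups used median-of-ratios size factors for polyA RNA and the deposited size factors for small RNA, with exact Clopper-Pearson intervals at 95% from the split of a gene's reads between both groups. A fold against a group with 0 reads was computed against a floor of 3 reads in that group. This floor is a 1-sided bound, so such a fold lies above the lower limit of the 2-sided interval. For a named gene in the difference between the lines, a direction was read where the intervals of both lines lay apart, a rule added after the values were seen. The correlation of ratios across genes was computed only between ratios that share no group.

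Fixed lists (26 of genes and 24 of miRNAs) were written before the data were examined, as were the groups, the comparisons and the alternatives in pseudocount, filter, scaling and threshold. A list median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, with seed 7, where at least 5 members were measured. Random lists give a rank and no p-value, since genes of a list are correlated. Alternatives chosen after seeing the data were ratios relative to the median gene, leaving out genes listed at 0 despite reads, recovered reads in place of FPKM, and 1 arm per mature miRNA.

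Named genes were the 10 highest and 10 lowest of each polyA comparison with at least 10 FPKM in the higher group, the 6 highest and 6 lowest miRNA arms with a value of at least 100, a few genes fixed before the data were examined, and at most 4 members of each list. An exception was added after the values were seen: a gene at either end of a polyA comparison also had to pass 2-fold in the same direction in recovered reads (scaled to library size, with 1 added) and not be listed at 0 despite reads. It passed over 45 genes for AFT024 exosomes against cells, 60 for BFC012 exosomes against cells, 26 for the cells, 23 for the exosomes and 61 for the difference between the lines. Not every gene that this rule names is reported here.

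The steps were tested on simulated data of 43629 genes and 2386 miRNA arms in 8 comparisons with at most 200 changed. At 4-fold at least 97.9% of changed polyA genes and 90.9% of changed miRNA arms were called in the right direction, and at 16-fold 100% of both. Of unchanged genes 0% passed 2-fold, and of unchanged miRNA arms at most 0.521%. Genes and arms were scored only where enough reads were expected in both groups, which left 10680 to 12699 unchanged genes and 176 to 439 unchanged arms. The simulation held counting error only and no conversion to FPKM. These rates therefore do not cover genes with few reads or differences between libraries. Lists raised 4-fold reached at least percentile 99.85, and 9 of 160 random lists lay outside the middle 95%. Reads were recovered exactly for 100% of values.

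Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.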

Results

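RNA was measured in AFT024 and BFC012, both stromal cell lines from C57BL/6 mouse fetal liver of 14.5 dpc (days post coitum), and in the exosomes that each line released. Exosomes are small membrane vesicles secreted by cells. Per the labels AFT024 supports hematopoietic stem and progenitor cells (HSPC) and BFC012 does not. With 1 line of each kind, a difference between the lines cannot be assigned to this support. Cells and exosomes of each line were sequenced as polyA RNA and as small RNA, which gave 8 groups with 2 samples each in the labels. The deposited tables hold 1 merged value per group. No difference given here therefore has a replicate check, and no p-value was computed from these values.

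The polyA tables held 9038471 reads for AFT024 exosomes, 16344350 for BFC012 exosomes, 39385534 for AFT024 cells and 35874383 for BFC012 cells. The small RNA tables held 1120450, 1247068, 17293776 and 17547485 reads in the same order. A floor of 3 reads corresponds to 0.332, 0.184, 0.0762 and 0.0836 RPM (reads scaled to library size) for polyA RNA and to 2.68, 2.41, 0.173 and 0.171 for small RNA. The 10 genes with the most reads took 11.9% of the polyA reads of AFT024 exosomes and 11.2% of those of BFC012 exosomes, against 4.35% and 4.77% in the cells. Kif1c, a kinesin motor gene, had the most reads in both exosome groups (3.76% and 3.86%), and Eef1a1, a translation elongation factor gene, in both kinds of cell (0.606% and 0.700%). Among the miRNAs, mir-22-3p led in exosomes (19.1% and 10.2% of reads) and mir-21a-5p in cells (18.2% and 11.0%). The FPKM table held 24544 genes, of which 14969 reached 1 FPKM in at least 1 group, and 818 of 2386 miRNA arms reached a value of 10 in at least 1 group.

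PolyA levels are given in FPKM and polyA log2 ratios as log2 of FPKM plus 1, relative to the median gene. The median gene itself stood at -1.11 for AFT024 exosomes against cells, -0.80 for BFC012 exosomes against cells, -0.23 for AFT024 against BFC012 exosomes and -0.28 for the difference between the lines in exosome-against-cell change. Read ratios are ratios of whole reads after median-of-ratios scaling, with exact Clopper-Pearson 95% intervals in brackets. Intervals and floors cover counting error only. A list member is called higher or lower where it passed 2-fold both as deposited and relative to the median gene. For exosomes against cells this asks for a larger rise than fall, because the median gene lies below 0, so the counts on the read scale are given as well. Each list median is placed among those of 10000 random lists matched on mean expression. A positive list median smaller than the shift of the median gene is negative as deposited. In all, 58 of 115 list medians for polyA RNA and 30 of 85 for small RNA lay outside the middle 95% of random lists.

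The comparison of the lines as cells asks how a supportive and a non-supportive stromal line differ in what they transcribe. AFT024 cells had much more Dlk1 and Peg10, both imprinted growth genes, together with Aqp1, a water channel gene. BFC012 cells had more of the mesothelial and urothelial genes Upk3b and Upk1b, the cadherin gene Cdh3, and Aldh1a1, a retinaldehyde dehydrogenase gene. Most collagens and cytokines that differed were higher in AFT024 cells, and the epithelial markers that differed were lower there.

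Dlk1 (mm10 chromosome 12, 109452822 to 109463336) stood at 931 FPKM in AFT024 cells and at 0.269 in BFC012 cells, a read ratio of 3070 (1617 to 6715). Peg10 (chromosome 6, 4747305 to 4760517) stood at 306 and 0.220 FPKM, a read ratio of 1406 (741 to 3076). The read ratio was 1012 (680 to 1580) for Aqp1 and 555 (370 to 876) for Postn, the gene of the matrix protein periostin. Smoc2, a secreted matrix protein gene, stood at 55.2 FPKM against 0.0341, Slc38a4, an amino acid transporter gene, at 157 against 1.37, Thbd, the thrombomodulin gene, at 68.3 against 0.235, and Col6a3 at 52.9 against 0.371. Ctsz had only 2 reads in BFC012 cells, and its read ratio was 2761 (764 to 22802). In the other direction, Upk3b (chromosome 5, 136038495 to 136045303) stood at 0.0482 FPKM in AFT024 cells and 139 in BFC012 cells, a read ratio of 0.00035 (0.000114 to 0.000816). Cdh3 gave a read ratio of 0.00131 (0.000735 to 0.00217) and Aldh1a1 one of 0.00564 (0.00399 to 0.00775). Upk1b had 0 reads in AFT024 cells and 3346 in BFC012 cells. The annexin gene Anxa8 stood at 4.28 and 164 FPKM, Myrf at 0.0943 and 53.9, Tenm3 at 0.0483 and 47.8, Vnn1 at 0.0187 and 35.8, Lphn2 at 0.0636 and 32.8, and Gpm6a at 0.0329 and 30.5.

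Of 14969 genes, 1128 were at least 2-fold higher and 890 at least 2-fold lower in AFT024 than in BFC012 cells. Of 38 collagens and matrix proteins 18 were higher and 5 lower, with a list median of 0.81 at percentile 100. Of 14 chemokines and cytokines 8 were higher and 2 lower, with a median of 2.46 at percentile 100. Among them Ccl2, a monocyte chemoattractant, had a read ratio of 7.27 (6.84 to 7.73) and Ccl7 one of 7.18 (6.44 to 8.02). HSPC-supporting niche factors went both ways, with 11 of 25 higher and 6 lower and a median of 0.12 at percentile 91.8. Cxcl12, the chemokine that retains stem cells in the niche, stood at 620 FPKM in AFT024 cells and 1540 in BFC012 cells, a log2 ratio of -1.29 and a read ratio of 0.405 (0.401 to 0.408). Kitl, which encodes stem cell factor, stood at 8.88 and 10.1 FPKM, and the growth factor gene Ptn at 142 and 28.7. Of 16 imprinted growth genes 6 were higher and 4 lower (median 0.69, percentile 100), among the lower ones Igf2 with 7 reads against 700. Mesenchymal stromal markers had 6 of 19 higher and 4 lower (median 0.50, percentile 99.9). All 4 measured epithelial markers were lower (median -1.29), among them Cdh1, the E-cadherin gene, at 0.0352 against 4.01 FPKM. These 4 reached 1 FPKM only in BFC012 cells, so the filter nearly fixed their direction. Of 5 hepatoblast and hepatocyte markers 4 were lower (median -1.40, percentile 0.66), among them Foxa2 at 0.103 against 11.7 FPKM and Trf, the transferrin gene, which was listed at 0 in AFT024 cells against 16.2. The only measured endothelial marker, Flt1, was lower at 2.72 against 11.5.

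Between the cells, immediate early genes had a median of 0.57 at percentile 100, with 5 of 21 higher and 1 lower. BMP and TGF-beta pathway genes had a median of 0.27 at percentile 99.4 (5 of 25 higher, 2 lower) and interferon-stimulated genes 0.49 at percentile 99.8 (2 of 17 higher, 0 lower). Replication-dependent histones stood at 0.61 and percentile 99.8 (4 of 19 higher, 1 lower), and Wnt pathway genes at 0.11 and percentile 86.0 (6 of 20 higher, 1 lower). Mitotic and proliferation genes had a median of -0.41 at percentile 0 although 0 of 25 were higher and 1 lower. Cytosolic ribosomal proteins stood at -0.15 and percentile 0.18 with 1 of 83 higher and 2 lower. Mitochondrial ribosomal proteins stood at 0.22 and percentile 100, with 2 of 74 higher and 1 lower. Among nuclear oxidative phosphorylation genes 1 of 71 was higher and 0 lower, and among the 28 vesicle biogenesis and marker genes 0 were higher and 2 lower. In the authors' deposited table, 1805 genes had q under 0.05 and at least 2-fold more in AFT024 cells, and 1344 in BFC012 cells, by a Fisher test of reads that compares libraries and not replicated conditions.

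The comparison of exosomes with the cells that released them asks which transcripts were over- or underrepresented in the vesicles. In both lines exosomes were rich in a set of very abundant transcripts that were at much lower levels in the cells, led by Sos2, a Ras exchange factor gene, Kif1c, Cdc42bpg, a kinase gene, and Trak2, an adaptor gene of mitochondrial transport. In both lines many collagen, other secreted matrix and contractile genes were lower in exosomes than in the cells. Cytosolic ribosomal protein transcripts stood above the median gene. Of the exosome marker genes, Cd63 was lower in exosomes of both lines, and Anxa2 was higher in BFC012 exosomes in reads.

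Sos2 (chromosome 12, 69583761 to 69681852) stood at 2214 FPKM in AFT024 exosomes and 13.0 in the cells, and at 3067 and 14.2 in BFC012. Its read ratio was 354 (338 to 372) in AFT024 and 331 (316 to 347) in BFC012. Kif1c (chromosome 11, 70700547 to 70731964) stood at 3159 FPKM in AFT024 exosomes against 44.7 in cells, a read ratio of 186 (182 to 189), and at 4370 against 49.0 in BFC012, a ratio of 182 (178 to 185). Cdc42bpg gave 144.8 (134 to 156) and 172 (163 to 181), and Trak2 66.2 (64.2 to 68.3) and 83.5 (80.5 to 86.6). Rdh10, a retinol dehydrogenase gene, gave 80.3 in AFT024 and 120 (105 to 138) in BFC012. Cd209c (chromosome 8, 3940221 to 3954746), a C-type lectin gene, stood at 558 FPKM in AFT024 exosomes against 9.43 in the cells and at 23.7 against 16 in BFC012. The AFT024 exosomes also held Me3 at 178 FPKM against 3.84, Fgd3 at 315 against 17.1 and Zdhhc1 at 127 against 6.41. For BFC012, Kctd10 gave a read ratio of 56.1 (55.3 to 56.9), Arhgap11a 50.8 (49.6 to 52.1), Sh3pxd2a 40.5 (39.7 to 41.4) and Mturn 82.9 (70.7 to 97.8). Cnbd2 stood at 741 FPKM in AFT024 exosomes against 11.8 in the cells but had only 39 and 50 reads, a read ratio of 4.55 (2.91 to 7.06).

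**Figure D1:**
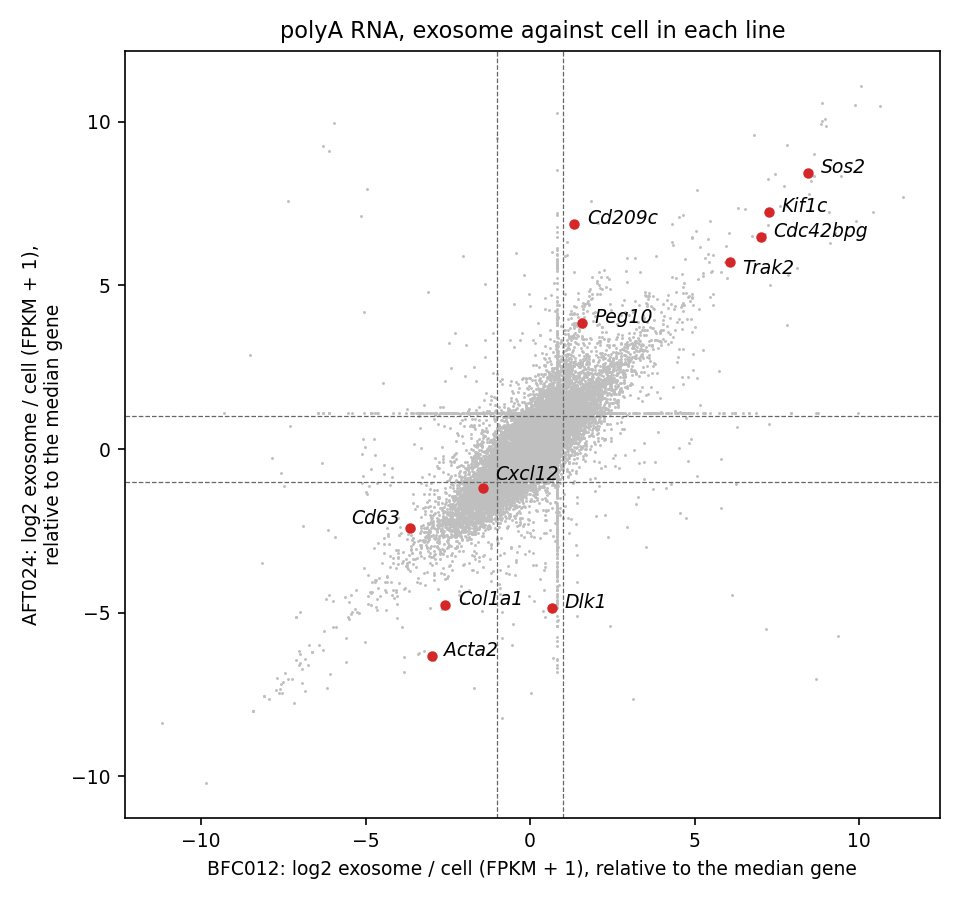
Each grey point is 1 of the 14969 genes that reached 1 FPKM in at least 1 group, with log2 of exosome against cell (FPKM plus 1, relative to the median gene) for BFC012 on the x axis and for AFT024 on the y axis; dashed lines mark 2-fold and red points are named genes. Sos2 and Kif1c lie far above 0 in both lines, Cd209c and Dlk1 lie off the diagonal, and straight rows of points are genes with 0 or nearly 0 FPKM in exosomes and cells of 1 line.

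Among the transcripts that were scarce in exosomes, Acta2, the smooth muscle actin gene, stood at 2.69 FPKM in AFT024 exosomes against 642 in the cells, a read ratio of 0.00956 (0.00758 to 0.0119). In BFC012 it stood at 51.0 against 719, a ratio of 0.141 (0.135 to 0.147). The contractile genes Tagln and Myl9 gave 0.00688 and 0.0133 in AFT024. Col1a1 gave 0.0347 (0.0316 to 0.0380), Col5a2 0.0395 (0.0358 to 0.0435) and Postn 0.00128 (0.000263 to 0.00373), the last from 3 exosome reads. Dlk1, at 931 FPKM in AFT024 cells, stood at 13.8 FPKM in their exosomes, a ratio of 0.0458 (0.0401 to 0.0521), and Slc38a4 at 2.26 against 157. Pabpn1, a polyA-binding protein gene, was listed at 0 in both exosome groups against 209 and 188 FPKM in cells, with 8 and 17 exosome reads. In BFC012, Col4a1 gave 0.0203 (0.0166 to 0.0245), Asah1 0.0468 (0.0375 to 0.0578), Emp1 0.053 (0.0485 to 0.0578), Pdia3 0.0716 (0.0650 to 0.0786) and Atp1b1 0.0732 (0.0672 to 0.0797). Ccdc47 stood at 1.95 against 86.8 FPKM and Vps29 at 5.31 against 220, where the read ratio of Vps29 was only 0.315. Hotairm1 had 1 read in BFC012 exosomes and 104 in the cells, a ratio of 0.0299 (0.000749 to 0.17).

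As deposited, 1154 genes were higher and 8014 lower in AFT024 exosomes than in the cells, and 1231 higher and 6665 lower in BFC012. Relative to the median gene the split was 3585 and 3374 in AFT024 and 2996 and 3415 in BFC012. It was 2924 and 3634, and 2736 and 3566, after median-of-ratios scaling, 3079 and 3238, and 3015 and 3171, after quantile scaling, and 2455 and 3077, and 2555 and 2844, in reads. Without ribosomal protein genes in the scaling it was 1560 and 6595 in AFT024 and 2197 and 4553 in BFC012. The changes of the lines correlated across genes (Spearman rho 0.75, Pearson r 0.71), where genes are not independent replicates. In both lines 565 genes were higher, against 94.9 if the lines were independent, and 5732 were lower, against 3568. Relative to the median gene 2221 were higher in both, against 718, and 2311 lower, against 770. Of the 565 genes 555 could be matched to a transcript, and 371 of these were also past 2-fold in reads in both lines. In the authors' deposited tables, 2739 genes with q under 0.05 were at least 2-fold higher and 3783 lower in AFT024 exosomes, and 2882 and 3986 in BFC012, with the same limit of a library comparison.

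Of 38 collagens and matrix proteins, 28 were lower and 0 higher in AFT024 exosomes than in the cells (median -2.36, percentile 0), and 21 lower and 0 higher in BFC012 (median -1.27, percentile 0). In reads 32 of 41 were lower and 0 higher in AFT024, and 28 lower and 1 higher in BFC012. Sparc, a matrix glycoprotein gene, stood at 28 FPKM in AFT024 exosomes against 1048 in cells and at 36.1 against 696 in BFC012, with read ratios of 0.0642 (0.0604 to 0.0682) and 0.103 (0.0982 to 0.108). Fn1, the fibronectin gene, stood at 43.3 against 410 and at 121 against 526. Of 14 smooth muscle and contractile genes 9 were lower in AFT024 and 7 in BFC012, with 0 higher in either line (medians -1.61 and -1.09, percentiles 0 and 0.32), and in reads 9 and 7 of 15 were lower and 0 and 1 higher. HSPC-supporting niche factors had 11 and 12 of 25 lower and 0 higher (medians -0.39 and -0.92, percentiles 1.65 and 0.03), and in reads 14 and 12 of 27 lower and 3 and 2 higher. Cxcl12 stood at 124 FPKM in AFT024 exosomes and 324 in BFC012 exosomes, with log2 ratios to the cells of -1.20 and -1.44. Its read ratios were 0.631 (0.616 to 0.646) and 0.502 (0.496 to 0.508), both short of 2-fold, the latter only just. Mitotic and proliferation genes had 16 of 25 lower in AFT024 (median -1.60, percentile 0) and 11 in BFC012 (median -0.74, percentile 7.67), with 0 higher. In reads 15 were lower and 1 higher in AFT024, and 9 lower and 4 higher in BFC012. Cdk1, for example, stood at 17.3 FPKM against 325 in AFT024. DNA replication genes had 16 of 22 lower and 1 higher in AFT024 (median -1.57, percentile 0.02) and 10 lower and 1 higher in BFC012 (median -0.95, percentile 2.30), and in reads 17 and 15 of 25 were lower and 1 higher in each line. BMP and TGF-beta pathway genes had 14 and 12 of 25 lower and 1 higher in each line (medians -1.28 and -0.96, percentiles 0.02 and 0.67). In reads 15 and 11 of 26 were lower and 3 and 4 higher, among the latter Grem1, a BMP antagonist gene, at 3.23 (3.11 to 3.36) in AFT024.

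The direction of the cytosolic ribosomal proteins depended on the scaling. Their median was 1.5 (percentile 100) in AFT024 and 0.52 (percentile 99.2) in BFC012 relative to the median gene, but 0.39 and -0.28 as deposited. Of 83 members 14 were higher and 0 lower in AFT024, and 1 was higher and 5 lower in BFC012. In reads, 57 of 85 were higher and 2 lower in AFT024, and 26 higher and 6 lower in BFC012. Rps2 stood at 7329 FPKM in AFT024 exosomes against 2334 in the cells, a read ratio of 7.20 (7.11 to 7.31), and at 3269 against 2450 in BFC012, a ratio of 2.56 (2.52 to 2.61). Nuclear oxidative phosphorylation genes had 21 of 71 lower and 1 higher in AFT024 (median -0.63, percentile 0.46) and 36 lower and 1 higher in BFC012 (median -1.08, percentile 0). Atp5a1, an ATP synthase subunit gene, went the other way, at 606 FPKM against 245 and at 1495 against 365. Mitochondrial ribosomal proteins had 24 and 37 of 74 lower and 1 higher in each line (medians -0.69 and -1.0, percentiles 2.94 and 0). In reads the AFT024 medians of both lists lay within random lists, at percentiles 20.9 and 30.4, with 10 of 77 and 13 of 75 lower and 5 and 4 higher. In BFC012 27 and 28 were lower and 4 and 1 higher in reads.

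Vesicle biogenesis and marker genes had 12 of 28 lower in AFT024 exosomes and 13 in BFC012, and 0 higher in either (medians -0.86 and -0.82, percentiles 1.04 and 3.36). In reads 10 and 8 of 30 were lower and 0 and 1 higher, the latter Anxa2, an annexin gene, at a ratio of 2.67 (2.64 to 2.71) in BFC012. Cd63, a tetraspanin marker of exosomes, stood at 41.7 FPKM against 491 in AFT024 and 13.9 against 328 in BFC012, with read ratios of 0.228 (0.208 to 0.249) and 0.0888 (0.0777 to 0.101). Mesenchymal stromal markers had 8 of 19 lower in each line and 1 or 2 higher (medians -0.26 and -0.76, percentiles 15.5 and 1.84), and in reads 8 of 20 lower in each and 5 and 3 higher. Zeb1, a mesenchymal transcription factor gene, was higher in exosomes of both lines, with read ratios of 24.4 (23.0 to 25.9) in AFT024 and 20.7 (19.7 to 21.7) in BFC012. Chemokines and cytokines had 7 of 14 lower in AFT024 (median -0.83, percentile 1.5) and 4 in BFC012 (median 0.08, percentile 13.7), and in reads 6 and 3 lower and 1 higher in each. Imprinted growth genes had 6 of 16 lower and 1 higher in AFT024 (median -0.65, percentile 0.11) and 2 lower and 0 higher in BFC012 (median 0.15, percentile 18.8), and in reads 8 and 2 of 17 lower and 2 and 1 higher. Notch pathway genes had 1 of 10 higher in AFT024 (median 0.80, percentile 92.7) and 2 in BFC012 (median 0.90, percentile 98.2), and 0 lower, although the AFT024 median is negative as deposited. In reads 3 of 13 were higher and 2 lower in AFT024, and 5 higher and 0 lower in BFC012. Notch3 gave a read ratio of 33.9 (32.0 to 35.9) in AFT024.

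Of 5 nuclear-retained long noncoding RNAs 1 was lower in each line and 0 higher (list medians -0.56 and -0.48, percentiles 22.3 and 8.11), and in reads 3 and 1 of 7 were lower and 1 and 0 higher. Malat1 stood at 12.6 against 48.2 FPKM in AFT024 and 6.24 against 32.5 in BFC012, while Neat1 had a read ratio of 2.16 (2.07 to 2.25) in AFT024 and 0.806 (0.777 to 0.837) in BFC012. Replication-dependent histones had 1 and 2 of 19 lower (medians -0.23 and -0.13, percentiles 0.79 and 2.23). The medians of apoptosis regulators (-0.01 and 0.05), Wnt pathway genes (-0.02 and 0.76), interferon-stimulated genes (0.48 and 0.58), immediate early genes (0.00 and 0.19), lipid and sterol synthesis genes (0.26 and -0.42), hematopoietic cell markers (-0.02 and 0.00) and hepatoblast and hepatocyte markers (1.11 and 0.17) lay within the middle 95% of random lists in both lines. In reads more members of some of these lists were higher than lower in AFT024, with 8 and 4 of 31 apoptosis regulators, 6 and 2 of 20 interferon-stimulated genes and 7 and 1 of 21 lipid and sterol synthesis genes. Epithelial markers, with 4 members, had medians of 1.14 and -0.20 and 0 past 2-fold on both scales. Mitochondrially encoded genes could not be measured, since the FPKM table has 0 genes of the mitochondrial genome.

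**Figure D2:**
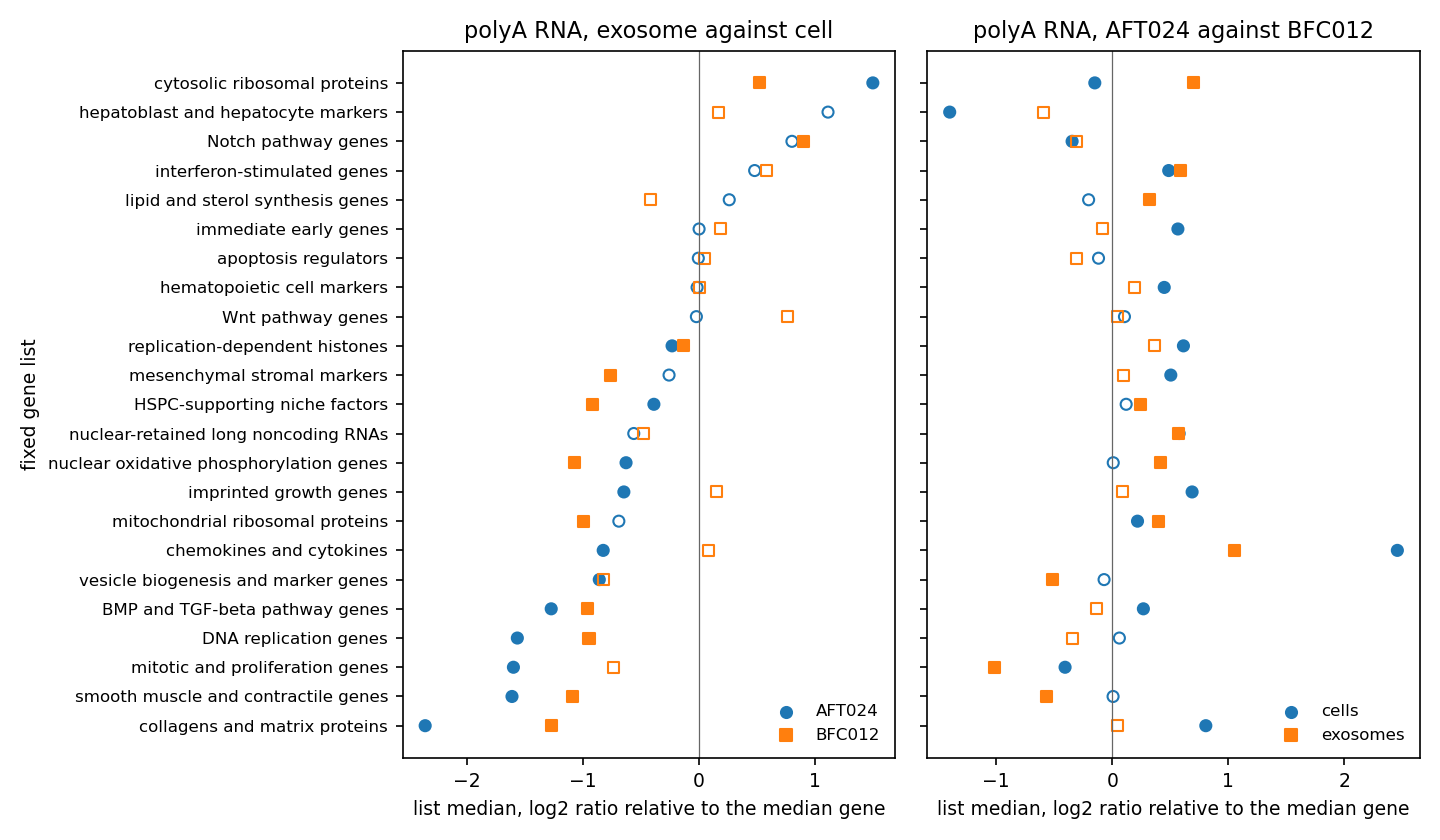
Points are the medians of the fixed gene lists on the x axis, as log2 ratio of FPKM plus 1 relative to the median gene, for exosomes against cells in each line (left panel) and for AFT024 against BFC012 in cells and in exosomes (right panel); filled points lie outside the middle 95% of 10000 matched random lists. Collagens and matrix proteins lie lowest in the left panel (-2.36 and -1.27), and the cytosolic ribosomal proteins there lie above 0, but at -0.28 in BFC012 as deposited.

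The comparison of exosomes of the lines asks which transcripts differ between AFT024 and BFC012 vesicles. AFT024 exosomes carried far more Peg10, Thbd, Col6a3 and Cd209c, and more of Lgals3, which encodes galectin-3, Igfbp6, an IGF-binding protein gene, and Mt2, a metallothionein gene. BFC012 exosomes carried more Tnc, the tenascin-C gene, Bicc1, Daam2, Akap5 and Nuak1. The mitotic genes that differed were lower in AFT024 exosomes, and more of the cytokines were higher there.

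Peg10 stood at 2058 FPKM in AFT024 exosomes and 1.08 in BFC012 exosomes, a read ratio of 1834 (1187 to 3003), and Thbd at 62.1 and 0.298, a ratio of 271 (190 to 403). Aqp1 gave 54.9 (39.8 to 78.0), Igfbp6 40.9 (28.4 to 61.1), Lgals3 31.7 (26.4 to 38.2), Mt2 30.8 (19.4 to 51.8) and Cd209c 29.5 (27.4 to 31.8). Col6a3 stood at 37.1 and 0.576 FPKM. The prolactin family genes Prl2c2 and Prl2c3, which are close paralogs, had 20 and 14 reads in AFT024 exosomes against 0, at least 11.7-fold and at least 8.16-fold higher against the floor of 3 reads, with lower interval limits of 8.63 and 5.80. Dlk1 was low in both but differed, at 13.8 and 0.143 FPKM, a ratio of 81.4 (34.4 to 253). Of the genes lower in AFT024 exosomes, Daam2 gave 0.0153 (0.0116 to 0.0199), Tnc 0.0163 (0.0126 to 0.0209), Bicc1 0.0172 (0.0142 to 0.0207), Akap5 0.0197 (0.0156 to 0.0244) and Kif26b 0.0216 (0.0178 to 0.0259). Nuak1 gave 0.0510 (0.0468 to 0.0556), Anxa8 0.0514 (0.0433 to 0.0606), Upk3b 0.00544 (0.00148 to 0.0140) and Plce1 0.00118 (0.000242 to 0.00344). Trf had 2 reads against 79, a ratio of 0.0442 (0.00527 to 0.165).

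As deposited, 1069 genes were higher and 2242 lower in AFT024 than in BFC012 exosomes. The split was 1456 and 1433 relative to the median gene, 1777 and 1424 after median-of-ratios scaling, 1560 and 1516 after quantile scaling, 1558 and 1600 in reads, 876 and 3545 without ribosomal protein genes in the scaling, and 317 and 387 at 4-fold. In the authors' deposited table, 1912 genes with q under 0.05 were at least 2-fold higher and 1811 lower, again between libraries. Line differences in cells and in exosomes correlated across genes with rho 0.39 and r 0.31, and across genes with reads rho was 0.573. In both cells and exosomes 312 genes were higher in AFT024, against 80.6 if independent, and 410 were lower, against 133.

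Of 25 mitotic and proliferation genes 13 were lower and 0 higher in AFT024 exosomes (median -1.01, percentile 0), among them Cdc20, an activator of mitotic exit, with a read ratio of 0.236 (0.219 to 0.255). DNA replication genes had 0 of 22 higher and 2 lower (median -0.34, percentile 20.1), and Rrm2, a DNA precursor enzyme gene, had a read ratio of 0.373 (0.347 to 0.401). Chemokines and cytokines had 6 of 14 higher and 2 lower (median 1.05, percentile 100), among them Ccl2 with a ratio of 18.5 (12.3 to 29.1). HSPC-supporting niche factors had 6 of 25 higher and 4 lower (median 0.25, percentile 97.9), with Cxcl12 lower at a ratio of 0.508 (0.496 to 0.521). Contractile genes had 4 of 14 lower and 0 higher (median -0.57, percentile 0.18), with Acta2 at 0.0612 (0.0483 to 0.0765). Collagens and matrix proteins had 5 of 38 higher and 10 lower (median 0.04, percentile 66.8), and vesicle genes 2 of 28 higher and 8 lower (median -0.52, percentile 0.82). Mesenchymal stromal markers had 3 of 19 higher and 1 lower (median 0.10, percentile 60.3), with Nes, the nestin gene, at 16.2 (15.1 to 17.5). Among BMP and TGF-beta pathway genes 2 of 25 were higher and 8 lower (median -0.14, percentile 31.1), and among Notch pathway genes 1 of 10 was higher, Notch3 at 10.2 (9.68 to 10.9), and 2 lower. In reads collagens had 14 of 41 higher and 11 lower, chemokines and cytokines 8 of 14 higher and 1 lower, mitotic genes 10 of 25 lower and 0 higher, and Notch pathway genes 4 of 13 higher and 6 lower.

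Cytosolic ribosomal proteins had 5 of 83 higher and 0 lower in AFT024 exosomes (median 0.70, percentile 98.5), and 21 higher and 0 lower in reads. Nuclear oxidative phosphorylation genes had 3 of 71 higher and 2 lower (median 0.42, percentile 99.6), and mitochondrial ribosomal proteins 6 of 74 higher and 1 lower (median 0.40, percentile 100). Interferon-stimulated genes had 4 of 17 higher and 0 lower (median 0.59, percentile 99.6), and 12 of 20 higher and 1 lower in reads. The lipid and sterol synthesis list stood at 0.32 and percentile 98.1 with 1 of 20 higher and 0 lower, and the nuclear-retained long noncoding RNAs at 0.57 and percentile 99.3 with 0 of 5 past 2-fold. Of imprinted growth genes 4 of 16 were higher and 4 lower (median 0.09, percentile 31.1), and of apoptosis regulators 1 of 30 higher and 5 lower (median -0.31, percentile 8.64).

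The difference between the lines in their exosome-against-cell change asks whether vesicle content followed cell content alike in both. Slc38a4, Aqp1, Dlk1 and Postn, which marked AFT024 cells, and Tnc and Acta2 had a lower exosome-against-cell ratio in AFT024 than in BFC012. Cd209c and Igfbp4, an IGF-binding protein gene that marked BFC012 cells, had a higher one in AFT024. For some of the genes named below, 1 of the lines had too few reads for a direction.

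The log2 difference was -4.49 for Slc38a4, -3.67 for Tnc, -3.37 for Acta2 and -3.27 for Aqp1, and it was 5.49 for Cd209c and 4.53 for Igfbp4. Since 1 FPKM was added to each value, a gene near 0 in cells and exosomes of 1 line enters with a change near 0 there. Aqp1 and Slc38a4 were low in BFC012, at 0.548 and 0.337 FPKM in exosomes and 0.222 and 1.37 in cells. The read ratio of Aqp1 was 0.267 (0.252 to 0.283) in AFT024 and 4.92 (2.88 to 8.57) in BFC012. That of Slc38a4 was 0.0431 (0.037 to 0.0499) and 0.504 (0.346 to 0.716). For Postn, Dlk1, Smoc2 and Sgce, with differences of -6.09, -5.54, -5.06 and -3.86, BFC012 exosomes had at most 7 reads, but the read ratios of the lines had intervals that lay apart: 0.00128 (0.000263 to 0.00373) in AFT024 and 0.540 (0.136 to 1.58) in BFC012 for Postn, and 0.0458 (0.0401 to 0.0521) and 1.73 (0.454 to 5.74) for Dlk1. The intervals give these genes a direction within counting error only and no size, and there is no replicate check. Hotairm1, Gpm6a and Sod3 had at most 7 reads in AFT024 exosomes, with intervals that lay apart the other way. The intervals overlapped for Cxcl5, Cdh3, Nt5e, Fxyd3, Igfbp2, Vnn1 and Peg10, so no direction is given for them. Peg10 was higher in AFT024 exosomes than in the cells at a read ratio of 9.01 (8.81 to 9.20), and gave 6.91 (3.01 to 17.2) in BFC012. As deposited, 1147 genes had a difference of at least 2-fold upward and 2351 downward. The split was 1787 and 1335 relative to the median gene, 1776 and 1301 after median-of-ratios scaling, 1508 and 1349 after quantile scaling, 948 and 1203 in reads, 915 and 3387 without ribosomal protein genes in the scaling, and 423 and 513 at 4-fold.

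Collagens and matrix proteins had 17 of 38 with a lower and 2 with a higher ratio in AFT024 (median -0.73, percentile 0), where members near 0 in 1 line such as Postn are counted too, and contractile genes 5 of 14 lower and 0 higher (median -0.64, percentile 0.28). Mitotic genes had 6 of 25 lower and 0 higher (median -0.49, percentile 0.59). Cytosolic ribosomal proteins had 10 of 83 higher and 1 lower (median 0.87, percentile 99.5), and 31 higher and 1 lower in reads. The medians of Wnt pathway genes (-0.59, percentile 0.10), immediate early genes (-0.60, percentile 0.06), lipid and sterol synthesis genes (0.48, percentile 99.8) and mitochondrial ribosomal proteins (0.21, percentile 99.8) also lay outside random lists, with at most 3 members of each past 2-fold in 1 direction.

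For miRNAs, levels are the deposited signal of the table of all groups. Log2 ratios are taken as deposited after adding 1, and read ratios use the deposited size factors. The cells of the lines differed in imprinted miRNA clusters. AFT024 cells expressed the miRNAs of the Dlk1-Dio3 cluster, an imprinted cluster beside Dlk1, which were nearly silent in BFC012 cells. BFC012 cells had more of the Sfmbt2 cluster, which holds the miR-297, miR-466, miR-467 and miR-669 families, and of mir-196b-5p and mir-351-5p. AFT024 cells also had more of the miR-181 family and of miR-199 and miR-214.

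Of 56 Dlk1-Dio3 arms 53 were higher in AFT024 cells and 0 lower (median 4.62, percentile 100). The read ratio was 288 (189 to 466.4) for mir-434-3p, 311 (106 to 1509) for mir-431-5p, 144 (101 to 213.6) for mir-541-5p and 53.2 (45.6 to 62.4) for mir-127-3p. Outside the cluster, mir-676-3p gave 552 (316 to 1069), and mir-676-5p had 961 reads in AFT024 cells and 0 in BFC012 cells, at least 323-fold higher. Of 75 Sfmbt2 cluster arms 68 were lower in AFT024 cells and 1 higher (median -1.93, percentile 0), among them mir-467d-5p at a signal of 103 against 373 and mir-466g-3p at 36.3 against 207. The ratio was 0.0221 (0.0208 to 0.0235) for mir-196b-5p and 0.142 (0.140 to 0.143) for mir-351-5p, and mir-196a-1-3p had 0 reads in AFT024 cells against 571. The arms of mir-760 parted, with 1322 reads of mir-760-5p in AFT024 cells against 0, and 7 reads of mir-760-3p against 1338.

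All 8 arms of miR-199 and miR-214 were higher in AFT024 cells (median 1.17, percentile 100), as were 8 of 11 of miR-181 with 0 lower (median 1.97, percentile 100), and mir-181a-2-5p gave a read ratio of 6.36 (6.22 to 6.50). Of 10 arms of miR-10 and miR-196, which lie in the Hox gene clusters, 5 were lower and 1 higher (median -1.01, percentile 0.14). Of 15 arms of miR-15 and miR-16, a family that restrains the cell cycle, 6 were lower and 0 higher (median -0.28, percentile 15.9), and of the 4 of the miR-200 family, an epithelial family, 3 were lower (median -1.49). The let-7 family had 2 of 26 higher and 2 lower (median -0.21, percentile 25.1), and the miR-17 to miR-92 clusters had 0 of 21 past 2-fold (median -0.48, percentile 1.04). The miR-21 arms (median 0.81), miR-29 (0.02), miR-30 (-0.25) and the smooth-muscle miR-143 and miR-145 (0.31) had 0 past 2-fold. In all, 165 arms were higher and 153 lower, 202 and 113 without the 5 most abundant small RNAs in the scaling, and 95 and 55 at 4-fold. In the authors' deposited table, 300 arms with q under 0.05 were higher and 281 lower in AFT024 cells, between libraries.

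In exosomes against cells, both lines showed high levels of miRNAs of blood cells that were scarce in the cells, led by mir-451a-5p, an erythroid miRNA, mir-142a-5p and mir-223-3p, which are made in leukocytes, and mir-144-5p, an erythroid miRNA. The most abundant cell miRNA, mir-21a-5p, and most of the let-7 and miR-30 families were lower in exosomes. The Dlk1-Dio3 miRNAs were higher in BFC012 exosomes than in BFC012 cells and went both ways in AFT024. The median arm of AFT024 stood at -0.22.

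The signal of mir-451a-5p was 29355 in AFT024 exosomes against 8.90 in the cells, a read ratio of 3298 (2233 to 5099), and 13508 against 13.4 in BFC012, a ratio of 1008 (733 to 1426). In AFT024 mir-142a-5p gave 903 (600 to 1427), mir-223-3p 481 (204 to 1491) and mir-144-5p 330 (207 to 559), and the last gave 637 (247 to 2352) in BFC012. The hepatocyte miRNA mir-122-5p had 91 reads in AFT024 exosomes and 0 in the cells, at least 228-fold higher, and 138 reads against 1 in BFC012, a ratio of 1040 (184 to 41388). The ratio of mir-10b-5p was 85.6 (79.0 to 92.9) in AFT024 and 141 (126 to 158) in BFC012, that of mir-486a-5p, an erythroid miRNA, 29.5 (28.7 to 30.2) and 5.80 (5.71 to 5.89), and that of mir-127-3p 6.96 (6.75 to 7.18) and 292 (250 to 343). In BFC012, mir-412-5p was at least 510-fold higher, mir-494-3p gave 590 (228 to 2179) and mir-369-3p 170 (126 to 237). In the other direction mir-21a-5p gave 0.120 (0.119 to 0.121) in AFT024 and 0.0875 (0.0864 to 0.0887) in BFC012, and mir-143-3p 0.147 (0.145 to 0.149) and 0.228 (0.225 to 0.231). In AFT024, mir-434-3p had 3 reads in exosomes and 6002 in cells, a ratio of 0.00376 (0.000774 to 0.0110), and mir-541-5p gave 0.0105 (0.00386 to 0.0230). In BFC012, mir-92a-1-5p gave 0.0427 (0.0351 to 0.0515). The passenger arm mir-143-5p had 0 reads in both exosome groups against 708 and 395 in the cells.

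**Figure D3:**
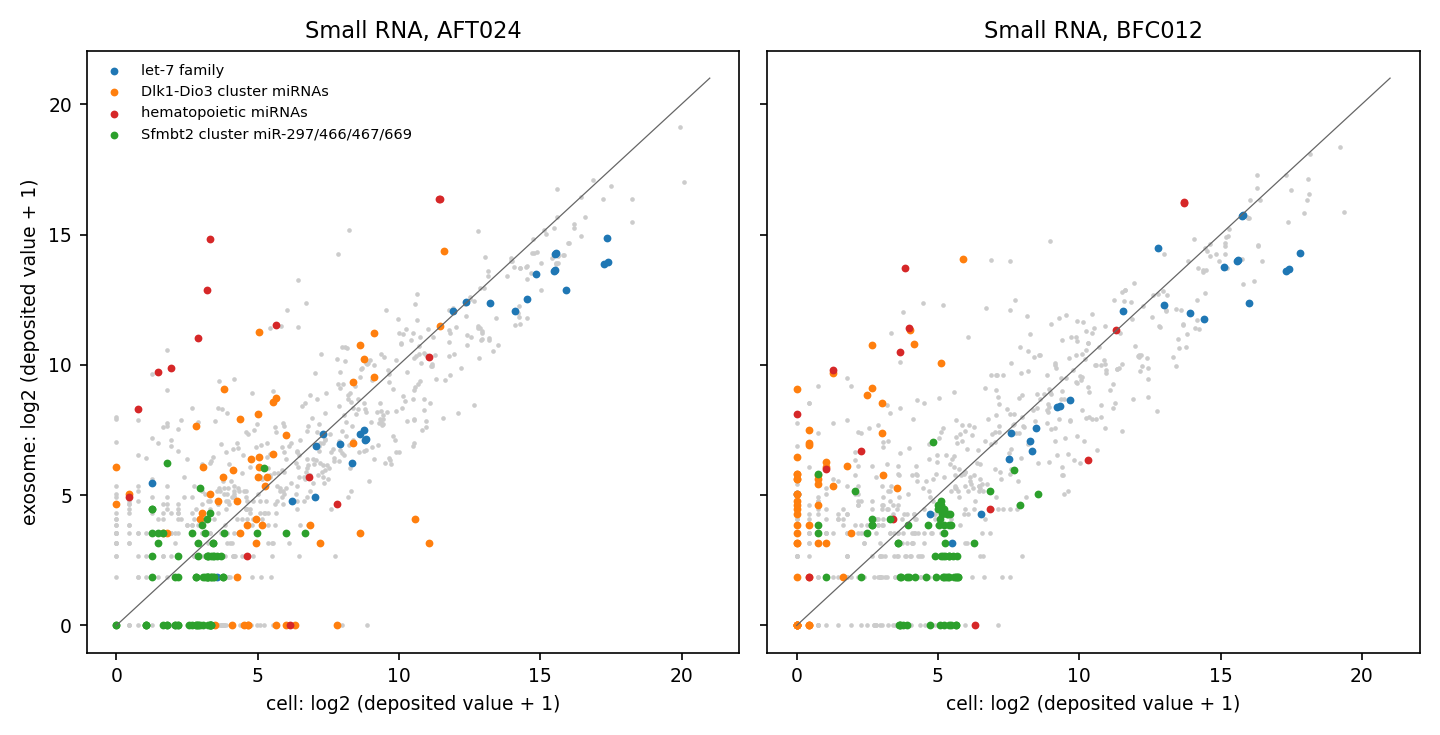
Each point is 1 of 818 miRNA arms, with log2 of the deposited signal plus 1 in cells on the x axis and in exosomes on the y axis for AFT024 (left) and BFC012 (right); the line marks equal levels and colours mark 4 fixed lists. Most let-7 arms lie below the line (19 and 15 of 26 lower), 10 of 15 hematopoietic arms lie above it in each line, and Dlk1-Dio3 arms lie above it in BFC012 (45 of 56) and on both sides in AFT024.

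Of 15 hematopoietic miRNA arms 10 were higher and 3 lower in each line (medians 4.95 and 2.54, percentiles 100 and 100). Of 18 arms of miRNAs abundant in serum and red cells, a list that shares members with it, 10 were higher and 6 lower in AFT024 and 10 higher and 4 lower in BFC012 (medians 3.63 and 1.65, percentiles 100 and 99.9). Of 4 muscle arms 3 were higher in AFT024 and 4 in BFC012 (medians 5.39 and 3.78), with mir-133a-1-3p at 201 against 2.49 in AFT024, and of 2 endothelial arms 2 and 1 were higher. Hepatocyte arms went both ways, with 3 of 8 higher and 2 lower in AFT024 and 3 higher and 4 lower in BFC012. Of 56 Dlk1-Dio3 arms 28 were higher and 18 lower in AFT024 (median 0.98, percentile 98.4), against 45 higher and 0 lower in BFC012 (median 4.43, percentile 100).

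Among the lists that went down, the let-7 family had 19 of 26 lower and 1 higher in AFT024 (median -1.55, percentile 0.94) and 15 lower and 2 higher in BFC012 (median -1.15, percentile 7.54). Its member let-7i-5p stood at 29761 against 170230 and at 19938 against 231746, while let-7b-5p stood at 23091 against 7057 in BFC012. Of 12 miR-30 arms 9 were lower in AFT024 and 11 in BFC012, with 0 higher (medians -1.67 and -2.43, percentiles 2.25 and 0.14). The Sfmbt2 cluster had 35 of 75 lower and 9 higher in AFT024 (median -1.05, percentile 0.93) and 50 lower and 9 higher in BFC012 (median -2.07, percentile 0). Neural arms had 6 of 12 lower and 1 higher in each line (medians -1.40 and -1.73, percentiles 3.71 and 0.27), and miR-181 had 7 of 11 lower and 0 higher in AFT024 (median -1.95, percentile 0.91) and 6 lower and 2 higher in BFC012 (median -1.11, percentile 5.66). Both miR-21 arms were lower in both lines (medians -2.94 and -3.58). Of the 4 arms of miR-221 and miR-222, 3 were lower and 1 higher in each line, the higher one being mir-221-3p. The miR-17 to miR-92 clusters had 7 of 21 lower and 3 higher in AFT024 and 12 lower and 1 higher in BFC012 (percentiles 44.3 and 1.90). The medians of miR-10 and miR-196, miR-15 and miR-16, miR-23 with miR-24 and miR-27, miR-29, miR-34, miR-99 with miR-100 and miR-125, and miR-199 with miR-214 lay within the middle 95% of random lists in both lines.

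In AFT024 251 arms were higher and 291 lower, and in BFC012 291 were higher and 268 lower. Without the 5 most abundant small RNAs in the scaling the split was 331 and 175, and 355 and 186. The changes of the lines correlated across arms (rho 0.72, r 0.72), with 193 arms higher in both, against 89.3 if independent, and 189 lower in both, against 95.3. In the authors' deposited tables, 285 arms with q under 0.05 were at least 2-fold higher and 176 lower in AFT024 exosomes, and 372 and 194 in BFC012, between libraries.

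Between the exosomes of the lines, AFT024 exosomes had more mir-676, mir-672-5p, mir-344b-3p and mir-221-3p, and more of several blood cell miRNAs. BFC012 exosomes had more of the Hox cluster miRNAs mir-196b-5p and mir-196a-1-3p and of mir-146b-5p and mir-351-5p. The Dlk1-Dio3 miRNAs, which set the cells apart, did not set the exosomes apart to the same extent, with 17 of 56 higher and 12 lower in AFT024 (median 0.20, percentile 91.9).

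The read ratio was 270 (91.9 to 1310) for mir-676-3p, from 804 reads against 3, and mir-676-5p was at least 16.4-fold higher. It was 121 (21.3 to 4807) for mir-672-5p, 34.7 (13.3 to 129) for mir-344b-3p, 4.07 (3.92 to 4.23) for mir-221-3p, 2.69 (2.51 to 2.90) for mir-142a-5p, 2.17 (2.10 to 2.25) for mir-451a-5p and 2.25 (2.22 to 2.29) for mir-21a-5p. It was 0.0359 (0.0251 to 0.0499) for mir-196b-5p, 0.0521 (0.0425 to 0.0633) for mir-146b-5p and 0.0869 (0.0844 to 0.0894) for mir-351-5p. For mir-127-3p of the Dlk1-Dio3 cluster it was 1.27 (1.23 to 1.31), compared with 53.2 between the cells. The signal of mir-503-5p was 13.4 against 234, and mir-1948-5p was at least 13.4-fold higher.

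Of 15 hematopoietic arms 9 were higher and 3 lower in AFT024 exosomes (median 1.12, percentile 99.9), and all 4 arms of miR-221 and miR-222 (median 1.97) and both miR-21 arms (median 1.45) were higher. The miR-181 family had 2 of 11 higher and 0 lower (median 0.81, percentile 99.1). Of 10 arms of miR-10 and miR-196 8 were lower and 1 higher (median -2.86, percentile 0), of 15 arms of miR-15 and miR-16 7 lower and 0 higher (median -0.97, percentile 0.18), and of 75 Sfmbt2 arms 38 lower and 10 higher (median -1.09, percentile 0.06). The let-7 family had 6 of 26 lower and 1 higher (median -0.13, percentile 29.0). In all, 198 arms were higher and 192 lower. The line differences in cells and in exosomes correlated across arms with rho 0.39 and r 0.39, with 76 arms higher in AFT024 in both, against 39.9 if independent, and 81 lower, against 35.9. In the authors' deposited table, 104 arms with q under 0.05 were at least 2-fold higher and 82 lower, between libraries.

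The exosome-against-cell change of miRNAs differed between the lines by at least 2-fold in 405 arms, in 183 of them upward. Of 56 Dlk1-Dio3 arms 50 had a lower and 4 a higher change in AFT024 than in BFC012 (median -4.17, percentile 0), and of 75 Sfmbt2 arms 36 had a higher and 8 a lower one (median 0.80, percentile 99.9). The log2 difference was -10.58 for mir-434-3p, -9.42 for mir-341-3p, -8.68 for mir-540-3p, -8.20 for mir-541-5p, -8.06 for mir-134-5p and -5.36 for mir-127-3p, all of the Dlk1-Dio3 cluster, where each but mir-127-3p had at most 30 reads in either BFC012 group. It was 7.94 for mir-760-3p, 5.08 for mir-344d-3-5p, which had 1 read in BFC012 exosomes, and 3.49 for mir-144-3p. The value of mir-760-3p depends on AFT024 cells, where nearly all mir-760 reads were listed on the other arm. For mir-1948-5p, with 0 reads in BFC012 exosomes, the interval of the read ratio was 4.17 to 10.2 in AFT024 and reached up to 1.02 in BFC012. The miR-181 family had 7 of 11 lower and 1 higher (median -1.28, percentile 0.49), and hematopoietic arms 7 of 15 higher and 1 lower (median 0.80, percentile 98.0). The miR-30 family had 3 of 12 higher and 1 lower (median 0.67, percentile 98.5).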

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

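All tests in this part were chosen only after the results were seen. The difference between the lines in the results of the next paragraph was not tested, because each group has 1 merged value.

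Of polyA genes with at least 10 FPKM and miRNA arms with a value of at least 100 in a group, 27 and 12 moved in opposite directions from cells to exosomes in the lines, past 2-fold both as deposited and relative to the median. Genes listed at 0 despite reads were left out. The polyA genes were mostly small nucleolar and other short RNA genes with 0 FPKM in exosomes of 1 line, besides Vimp, Arhgap22 and Fyb. The log2 change from cells to exosomes was -3.02 in AFT024 and 5.04 in BFC012 for mir-134-5p, -7.89 and 2.69 for mir-434-3p, -4.04 and 4.64 for mir-540-3p, and -6.48 and 1.72 for mir-541-5p, with at most 30 reads in each BFC012 group. It was -7.82 and 1.61 for mir-341-3p and 2.64 and -3.49 for mir-1948-5p, but in BFC012 these had 4 and 0 exosome reads and their read ratios had intervals that include 1, so the opposite direction is not shown for them. Nor is it for mir-434-5p and mir-335-3p, with 1 read each in BFC012 exosomes. The remaining arms had higher signals in BFC012 exosomes. Their changes in AFT024 and BFC012 were -1.37 and 1.18 for mir-132-3p, -1.90 and 1.36 for mir-542-5p and -1.35 and 5.03 for mir-431-5p. They were -1.52 and 2.23 for mir-503-5p, which had a signal of only 13.4 in AFT024 exosomes. Xist, an X-linked noncoding RNA that the FPKM table leaves out with the rest of chromosome X, had 43076 recovered reads in AFT024 cells and 17 in BFC012 cells, and 201 in AFT024 exosomes and 17 in BFC012 exosomes.

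Exosomes of both lines were rich in Dlk1-Dio3 cluster miRNAs, although BFC012 cells had almost none: the 47 arms not known as rodent-specific summed to 36857 in AFT024 exosomes and 28314 in BFC012 exosomes, against 11027 and 179.5 in the cells. If these came from RNA of another species, arms known only from rodents should not be raised in exosomes. In AFT024 all 9 rodent arms were lower in exosomes than in the cells (median -4.66, range -7.89 to -1.76), whereas the others had a median of 1.28 with 28 higher and 9 lower, a difference of medians of -5.94 that is consistent with RNA of another species. In BFC012 4 of the 9 rodent arms were higher in exosomes and 0 lower, and their sum was 90.4 against 10.9 (log2 ratio 3.05, against 7.30 for the others). Of the 4, mir-434-5p had a signal of only 2.66 against 0.353, and the interval of the read ratio of mir-341-3p, 0.831 to 14.1, spanned equal levels. The intervals of mir-434-3p, 3.69 to 13.9, and of mir-540-3p, from 14.9 upward, lay above equal levels. RNA of a species that lacks mir-434-3p and mir-540-3p would not supply them. With 34 and 31 reads behind those sums, such a source for the other arms in BFC012 cannot be told apart from export by the cells, which was not tested in either line, and the labels do not state the serum.

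Exosomes of both lines held 37 miRNA arms at 100 or more that were at least 16-fold lower in the cells. The 37 arms made up 4.59% and 3.56% of the exosome values. The highest was mir-6240-3p, with a signal of 36601 in AFT024 exosomes and 27468 in BFC012 exosomes, above mir-451a-5p at 29355 and 13508. Also among them were mir-10b-5p, mir-6240-5p, mir-142a-5p, mir-223-3p and mir-122-5p. Mouse red blood cells in the cultures would bring globin mRNA. The 4 globin genes gave 1 read in AFT024 exosomes and 0 in BFC012 exosomes, at most 0.111 RPM. This argues against red blood cells only if reads shared by close paralogs among these genes were counted, and how such reads were counted is not given. A shared outside source should give both exosome groups the same profile, and the levels of these arms correlated between them with rho 0.797, against 0.872 for all arms. That value cannot be told apart from a profile that the exosomes share for other reasons, because all arms correlate as well, so an outside source and export by both lines stay open, and export was not tested.

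Sos2, Kif1c and the other polyA genes higher in exosomes than in cells in both lines (565, of which 555 were tested) could reflect how reads are counted. A few dominant genes with recovered reads, which would hold the others down in the cells, do not account for them. The 10 genes with the most reads took at most 4.77% of cell reads. This does not cover the 37 mitochondrially encoded genes, which had 0 recovered reads. Whether their reads count in the library size behind FPKM is not given. The tested genes had longer transcripts than the others, with medians of 3525 and 2662 bases. With the length trend removed from the FPKM ratios 87.2% still passed 2-fold in both lines. The medians went from 2.00 to 1.95 in AFT024 and from 2.18 to 2.12 in BFC012. The trend with length thus did not by itself bring the genes that stayed past 2-fold over that threshold. For the tested genes as a set length stays open, because the share that stayed fell between the limits set for either answer. However, 184 of the 555 did not pass 2-fold in reads in both lines, which leaves the conversion to FPKM open for these. Reads shared with repeated sequence cannot be told apart from a real excess: 30.1% of the genes held a stretch of 31 bases found in at least 20 other genes, at percentile 53.35 of 1000 matched lists (median 29.9%), which shows no excess but leaves open single genes, because where in a gene the reads lie is not in the tables. Selective loading into vesicles stays open and was not tested.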

How the results depend on the processing

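No paired analysis was possible because the columns hold merged values without replicate numbers. For the same reason leaving out single libraries, a replicate block and DESeq2 were not run, and the lists were placed among random lists. Of the counts and correlations recomputed under alternatives, 88 stayed the same, a count within 1.5 times and a correlation within its 95% interval, and 34 moved. A count here sums both directions, so a shift between them does not enter: for AFT024 exosomes against cells, median-of-ratios scaling took 1154 higher of 9168 changed genes to 2924 of 6558. Where no cause is given, the cause was not tested. Depth limits the exosome small RNA most, where 3 reads equal 2.68 and 2.41 RPM.

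With a threshold of 4-fold the numbers of changed polyA genes were 4305 for AFT024 and 3244 for BFC012 exosomes against cells, 805 between cells, 704 between exosomes and 936 for the difference between the lines, compared with 9168, 7896, 2018, 3311 and 3498 at 2-fold. For miRNA arms they were 299, 371, 150, 165 and 210, compared with 542, 559, 318, 390 and 405. Fewer genes pass a higher threshold by construction. Without a filter 932, 972, 518, 807 and 913 arms passed 2-fold, and with a filter of 100 there were 277, 273, 138, 164 and 156, where more or fewer arms entered.

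With pseudocount 5, 5211 polyA genes changed between BFC012 exosomes and cells, 999 between cells, 1470 between exosomes and 1747 in the difference between the lines. In recovered reads with median-of-ratios scaling, where 13300 genes entered, 5532 changed between AFT024 exosomes and cells and 2151 in the difference between the lines, and median-of-ratios scaling of FPKM alone gave 6558 for the former. The correlation across genes of line differences in cells and in exosomes was 0.351 with pseudocount 5, 0.374 for genes above the filter in all 4 groups and 0.573 in reads. That of exosome-against-cell changes was 0.788, 0.852 and 0.804. For miRNA arms above the filter in all 4 groups the values were 0.518 and 0.794.

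Among named genes past 2-fold as deposited and not listed at 0 despite reads, 17 polyA values turned direction and 0 miRNA values did. Changes of sign in values under 2-fold as deposited were not counted. All but 1 of the 17 concern AFT024 exosomes against cells, where the log2 ratio was negative as deposited. In reads it was 0.061 for Anxa2, 0.20 for Atp5g2, 0.29 for Atp5g3, 0.0046 for Birc5, 0.052 for Fzd2, 0.18 for Lrp6 and 0.058 for Tug1. After median-of-ratios scaling it was 0.22 for Atp5g3, 0.13 for Birc5 and 0.10 for Lrp6. After quantile scaling it was 0.17 for Fzd2, 0.035 for Kitl, 0.28 for Lrp6 and 0.18 for Tug1. Relative to the median gene it was 0.048 for Atp5g3 and 0.068 for Lrp6, which follows by construction, since every AFT024 ratio rises by 1.11. The difference between the lines for Notch3 was 1.01 with pseudocount 1 and -0.052 with pseudocount 0.1. The cause of the other turns was not tested. List medians outside the middle 95% numbered 58 of 115 for polyA RNA and 57, 51 and 54 of 120 against unmatched lists, with pseudocount 5 and in reads, and for small RNA 30 of 85, 27 against unmatched lists and 30 with pseudocount 10.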

Other observations

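The arms of mir-760 differed in direction between the cells of the lines, with a signal of 471 for mir-760-5p in AFT024 cells and 0 in BFC012 cells, and of 2.49 and 472 for mir-760-3p. In exosomes mir-760-5p was at 0 in both lines and mir-760-3p at 530 and 292. How reads were assigned to the arms in each group is not given, and the cause of this pattern was not tested.

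Other growth factor and matrix genes of the fixed lists differed between the cells. Gas6, a ligand of receptor tyrosine kinases, stood at 5.87 FPKM in AFT024 cells and 113 in BFC012 cells, and at 1.84 and 41.9 in the exosomes. Dcn, the decorin gene, stood at 4.18 and 46.1 FPKM in the cells and Tgfb3 at 5.94 and 32.4. Grem1, a BMP antagonist gene, stood at 39.1 and 17.2 in the cells and at 49.1 and 13.4 in the exosomes.

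Some niche factor genes were lower in exosomes than in the cells of both lines. Csf1, a macrophage growth factor gene, stood at 14.9 and 14.2 against 154 and 116 in the cells, and Fgf7 at 4.92 and 6.48 against 60.3 and 74.7. Kitl was low in exosomes and cells, and its read ratios were 0.926 (0.828 to 1.03) in AFT024 and 1.05 (0.969 to 1.14) in BFC012.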
